A study of Oryza sativa with 12 samples.

How the data were processed

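RNA from leaves of Nipponbare rice was sequenced in 12 libraries, 3 in each of 4 groups: long-day watered, long-day drought, short-day watered and short-day drought. Groups and replicates were read from the sample titles. Each library came from the tips of fully extended leaves of 2 to 3 plants, per the labels. Nothing in the labels links a library of one group with a library of another, so the replicates were not paired. The hour of harvest, the strand of the libraries and the genome build are not given in the sources used here.

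The deposited values of each library are raw read counts per locus made by the authors, with 55986 features, of which 55801 are rice loci and 185 carry other names. The submitters' processing notes name Bowtie2, TopHat2, HTSeq, R 3.1.2 and edgeR 3.6.8, without their roles. Reads that the deposited counts list as belonging to no gene (3.01% to 3.72% per library, as a share of all that were listed), as ambiguous (1.91% to 2.27%) or as not uniquely aligned (10.3% to 12.4%) were kept out of library sizes and tests. Reads without a unique position were not counted, so the counts of near-identical copies, such as the RAB16, small heat shock protein, aquaporin PIP and Rubisco small-subunit genes, are uncertain. The authors also deposited 5 tables of comparisons with a log2 fold change on the authors' own scaling. In the same tables the p-value and FDR columns were made by the authors with a likelihood ratio test. These tables were compared with the fit below but did not enter it. Their CPM and RPKM columns (120 columns over the tables) were not used, because their names give the group and not the sample.

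Total counts per library ran from 21428347 to 32854269, and 29384 to 30882 loci had at least 1 count. In a group with 0 counts, 3 counts over its libraries were taken as the floor, which is 0.0268 to 0.0445 CPM by group. Ratios against 1 to 3 counts are given with 95% counting intervals from the exact test of a ratio of Poisson rates. Intervals and floors cover counting error only.

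Counts were analysed in R 4.3.3 with edgeR 4.0.16. Loci were kept by filterByExpr (minimum count 10, minimum total 15), which left 23830, and libraries were scaled by TMM. A single model with 1 mean per group was fitted to all 12 libraries (glmQLFit, robust), and 6 comparisons were tested with the two-sided quasi-likelihood F test: drought in long days, drought in short days, day length in watered plants, day length in droughted plants, the interaction of drought and day length, and short-day drought against long-day watered plants. P-values were adjusted by Benjamini-Hochberg over all kept loci, with a threshold of 0.05, and counts are also given for changes of at least 2-fold. The standard error of a log2 fold change was taken as its size divided by the square root of F. The groups, the tests, the lists, the naming rule and the alternatives were set before the data were examined, except where stated. The test was checked on simulated data with 200 changed loci per comparison. It recovered 37% to 51% of changes of 1 on the log2 scale and 82% to 93% of changes of 2, and 4.14% to 6.29% of its calls were false. The simulated changes were balanced in direction, and each locus had 1 dispersion for all groups. In the data many more loci change under drought and the spread differs by group, so these rates need not hold there.

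The 14 gene lists were florigen and photoperiodic flowering, circadian clock, ABA metabolism and signalling, dehydration markers, drought-related transcription factors, heat shock proteins, photosynthesis, chlorophyll breakdown and leaf senescence, antioxidant enzymes, aquaporins, sugar transport and metabolism, pathogen response, shoot apical meristem markers, and guard cell markers. Of their 206 fixed members, 196 passed the filter. Lists were tested with camera from limma 3.58.1 (correlation 0.01, adjusted over the lists of a comparison), with camera at an estimated correlation and with fry. Families by product description were not formed, because the deposited files hold no descriptions. The pairs of symbol and locus in the lists were checked by position against an annotation table of 39387 genes, which holds 0 of these locus identifiers. Of 205 pairs, 132 lay within 1 Mb of the gene of that symbol, 68 had no such symbol in the table, 3 lay on another chromosome and 2 elsewhere on the same one. Symbols are printed for the 132 pairs and for Ehd1 and Ghd7, which rest on the fixed list alone. Other members appear under their locus identifier.

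The named genes are 9 flowering genes in every comparison and up to 4 members per list and comparison with the smallest adjusted p among those past the test. Added to these were up to 5 list members with a printed symbol per direction. They had the largest change among those with a mean of at least 5 CPM in the higher group and no overlap between groups. The loci with the largest changes under the same CPM and overlap conditions were also ranked over all loci, with or without a symbol. Chosen after their values were seen were TPP1, LOC_Os02g33820, LOC_Os12g17600, NYC1, HSP101 and SWEET15 in drought in long days, TPP1, HSFA2a, HSFA2d and HSP17.4 in drought in short days, and GI in droughted plants.

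The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, no filter, a filter of 1 CPM in 3 libraries, a fit of only the libraries compared, a term for libraries 9 to 12, a threshold of 0.01, and leaving out each library in turn. Library sizes without scaling factors, libraries thinned to 21428347 counts, list counts without long-day watered replicate 3, and leaving out each library outside a comparison were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.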

Results

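Messenger RNA was profiled by sequencing in leaves of rice (Oryza sativa cv. Nipponbare, a japonica cultivar) under every combination of day length and water supply. Plants spent their first 4 weeks in long days with regular watering, after which part of them moved to short days, the day length that induces flowering in rice. Under each day length, some plants stayed watered and others were held under drought for 13 days. Each of the 4 groups (long-day watered, long-day drought, short-day watered and short-day drought) held 3 libraries, and each library came from the tips of the youngest fully extended leaves of 2 to 3 plants. The series title names the florigen genes Hd3a and RFT1 and their activator Ehd1, so the comparisons ask how drought and day length act on these genes and on the rest of the leaf transcriptome. Between 21428347 and 32854269 reads were assigned to genes per library. The expression filter left 23830 loci.

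Levels are given in CPM, read counts relative to the TMM-scaled library size, with the SD of the 3 libraries of a group. Log2 fold changes carry the standard error of the fit, and p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested loci. Nothing in the labels ties the libraries to separate growth runs, so these p-values measure the spread between libraries, pooled over all groups of the fit. A change given without its adjusted p was past the threshold. Where a list has only 1 pair of counts, the counts adjusted over the list alone were equal to them.

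Water supply separated the libraries most. The component of log2 CPM that held 72.6% of the variance placed the 6 watered libraries between -140.9 and -101.2 and the 6 droughted libraries between 117.9 and 147.3. The next component, with 10.2%, separated watered plants by day length, while the droughted groups overlapped on it. Replicates within a group correlated at 0.938 to 0.987 across genes (Pearson's r of log2 CPM, with genes not being independent replicates). Long-day watered replicate 3 stood apart from its group, with r of 0.938 and 0.952 against the other replicates, which correlated at 0.985 with each other. In watered leaves the 10 most abundant loci took 9.60% to 11.6% of the counts, and in droughted leaves 4.59% to 5.83%. TMM scaling factors accordingly ran from 0.780 to 0.899 in watered and from 1.14 to 1.32 in droughted libraries. Scaling by library size alone shifts the median log2 fold change of all genes by 0.635 for drought in long days, by 0.446 for drought in short days and by 0.539 for short-day drought against long-day watered plants. All changes below are relative to the TMM scaling.

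**Figure D1:**
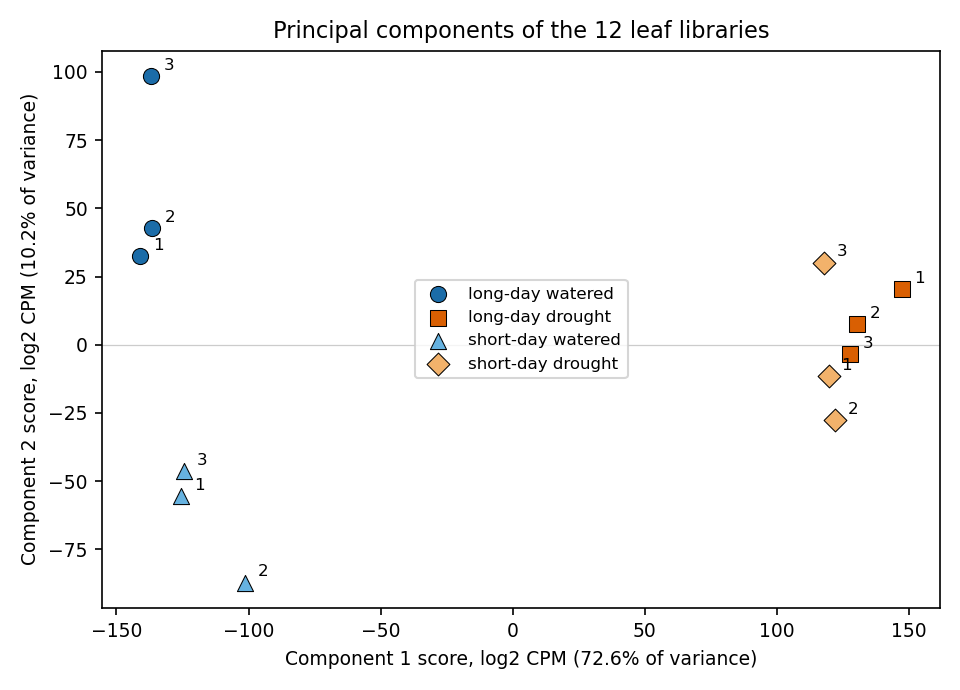
Scores of the 12 libraries on the first and second principal components of log2 CPM, 1 point per library with its replicate number, coloured by group. The watered and droughted libraries separate on the horizontal axis (72.6% of the variance), and the day lengths separate on the vertical axis (10.2%) in watered plants, where long-day watered replicate 3 lies at 98.46.

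The comparison of droughted with watered plants in long days asks how drought acts in the non-inductive day length. The florigen genes were at the limit of detection there with or without water. Hd3a (LOC_Os06g06320), which encodes the mobile protein that carries the flowering signal from the leaf, had 1 count in the 3 watered and 2 counts in the 3 droughted libraries. Its homolog RFT1 (LOC_Os06g06300) had 0 counts in both groups, and their activator Ehd1 (LOC_Os10g32600), a B-type response regulator, had 2 and 0. These totals lie under the floor of 3 counts per group (0.0445 CPM in watered and 0.0268 CPM in droughted leaves), so no fold is given and no change was detectable at this depth. Drought did move regulators upstream of them. Ghd7 (LOC_Os07g15770), a CCT-domain repressor of flowering in long days, fell from 4.35 ± 0.712 to 0.762 ± 0.0301 CPM (log2 fold change -2.51 ± 0.371, adjusted p = 0.000152). The CONSTANS homolog Hd1 (LOC_Os06g16370) rose from 5.995 ± 0.627 to 15.01 ± 1.25 CPM (1.32 ± 0.151, adjusted p = 2.24e-05).

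Among the 23 fixed genes of florigen and photoperiodic flowering, 5 rose and 9 fell under drought in long days (5 and 9 adjusted over the list alone; PRR37 is also a member of the clock list). That balance turned to 9 raised and 6 lowered with library sizes only. The list as a whole did not differ from other genes (camera adjusted p = 0.429). The SOC1-like flowering promoter MADS50 fell by 2.54 ± 0.121 on the log2 scale, and the AP1/FUL-like MADS-box genes MADS14 and MADS18 fell by 2.11 ± 0.415 and 2.82 (adjusted p = 0.00113 and 4.51e-06). PRR37 and DTH8, both repressors of flowering in long days, were not past the test at 0.17 (adjusted p = 0.344, past it with library sizes only at 0.81) and -0.88 (adjusted p = 0.173). Neither was MADS15 at 1.27 (adjusted p = 0.279). In the circadian clock list, 2 of 13 genes rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.429; 5 raised and 4 lowered with library sizes only). GIGANTEA (GI), a clock component that links the clock to flowering, rose from 70.2 ± 26.2 to 853 ± 61.1 CPM (3.603 ± 0.263, adjusted p = 1.09e-06). LHY, a morning-expressed repressor, and the pseudo-response regulator PRR95 both had log2 fold changes of -1.76. With library sizes only these were -1.12 and -1.11.

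Some genes that mark water loss rose by orders of magnitude under drought in long days. The dehydrin gene RAB16A went from 8.98 ± 5.68 to 6045 ± 1430 CPM (log2 fold change 9.40 ± 0.651, adjusted p = 8.99e-07). The late embryogenesis abundant protein gene LEA3 went from 4.06 ± 2.40 to 2104 ± 730 CPM (9.01 ± 0.592, adjusted p = 6.51e-07). SALT, a salt-induced lectin gene, went from 2.95 ± 3.52 to 1445 ± 980 CPM (8.92 ± 1.13, adjusted p = 5.37e-05). P5CS1, which makes the osmolyte proline, rose by 3.62. Of the 18 tested dehydration markers, 14 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.000107, but adjusted p = 0.3 with an estimated correlation). The lowered members were TPP1, a trehalose-6-phosphate phosphatase gene (-4.48), and LOC_Os02g33820 (-1.41). The list of abscisic acid (ABA) metabolism and signalling had 19 of 34 genes raised and 7 lowered (19 and 7 adjusted over the list alone; camera adjusted p = 0.0831). Its largest rise was that of the phosphatase gene PP2C51 (7.66 ± 0.555, adjusted p = 1.16e-06). The kinase gene SAPK3 rose by 2.86, and ABA8ox3, which encodes an enzyme of ABA breakdown, fell by 4.44 ± 0.259 on the log2 scale.

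Photosynthesis genes fell together. All 26 tested members were lowered under drought in long days (26 adjusted over the list alone), with a median log2 fold change of -3.58 (camera adjusted p = 4.46e-11, but adjusted p = 0.407 with an estimated correlation). RCA, the Rubisco activase gene, dropped from 38770 ± 8870 to 3754 ± 1190 CPM (-3.37), the light-harvesting gene CAB1R from 4800 ± 906 to 793 ± 215 CPM (-2.60) and the photosystem I gene PSAH by 2.27 on the log2 scale. The locus LOC_Os12g17600 had the list's largest drop, -7.02 ± 0.547. All 9 genes of chlorophyll breakdown and leaf senescence rose (9 adjusted over the list alone; median 2.2, camera adjusted p = 0.000385, adjusted p = 0.3 with an estimated correlation), among them RCCR1 (4.01 ± 0.24), the chlorophyll b reductase genes NOL (2.20) and NYC1 (1.41), and the stay-green gene SGR (1.88).

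The other stress groups moved in both directions in long days. Of 12 heat shock genes 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.429). HSP16.9B, a small heat shock protein gene, rose by 5.60 and the chaperone gene HSP101 by 2.86, whereas the heat shock factor genes HSFA2a and HSFA2d fell by 4.01 ± 0.498 and 3.59 on the log2 scale. Among drought-related transcription factors 5 of 11 rose and 4 fell (camera adjusted p = 0.429). DREB2A, a drought-responsive activator, rose by 2.54, and DREB1A, best known from cold, fell by 6.43 ± 1.14 on the log2 scale. Antioxidant enzymes were split 4 up and 4 down of 10 (camera adjusted p = 0.778), with median -0.176 and mean 0.149 of opposite sign (median 0.458 with library sizes only). The catalase gene CATB rose by 2.96 and the mitochondrial superoxide dismutase gene SODA1 by 2.67, and the chloroplast peroxidase gene APX8 fell by 2.14 on the log2 scale. In the aquaporin list 2 of 14 rose and 3 fell (camera adjusted p = 0.778; 4 and 2 with library sizes only). In sugar transport and metabolism 5 of 11 rose and 4 fell (camera adjusted p = 0.849). In pathogen response 2 of 9 rose and 5 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.476). Without long-day watered replicate 3 the raised and lowered counts were 3 and 5 for aquaporins, 3 and 4 for pathogen response and 3 and 5 for the clock list. The water channel gene PIP2;2 fell by 3.33, SWEET15, a sugar exporter gene, rose by 5.07, and the defence regulator gene WRKY76 fell by 2.62. Markers of other cells were checked too: all 4 tested shoot apical meristem and cell division genes fell (camera adjusted p = 0.0648), as did 1 of 2 guard cell genes (camera adjusted p = 0.429). In that meristem list MADS1 fell from 13 to 2 counts (ratio 10.8, counting interval 2.44 to 98.5; adjusted p = 0.0452), a call that ended under limma-voom (adjusted p = 0.143) and without long-day watered replicate 2 (adjusted p = 0.129) or 3 (adjusted p = 0.167) or long-day drought replicate 1 (adjusted p = 0.112) or 2 (adjusted p = 0.107), among other settings.

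In total, drought in long days raised 7763 loci and lowered 7636 of 23830, of which 4716 and 5557 changed by at least 2-fold. With library sizes only, the raised share of the calls went from 50.4% to 72.5%. Over all loci that met the CPM and overlap conditions of the naming rule, those with the largest fitted rise were LOC_Os08g18974 and LOC_Os03g48750. Those with the largest fitted fall were LOC_Os02g52930 and LOC_Os12g09720. LOC_Os08g18974 and LOC_Os03g48750 were at 0 CPM in watered leaves and LOC_Os12g09720 at 0 CPM in droughted leaves, so their ranks rest on fitted folds over 0.

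In short days, where the florigen genes are expressed, the comparison asks what drought does to them, and both fell. Hd3a fell from 44.5 ± 5.34 CPM in watered leaves to 0.544 ± 0.691 CPM in droughted leaves, 79.2-fold (log2 fold change -6.31 ± 0.671, adjusted p = 2.11e-05). The droughted libraries held 1.34, 0.173 and 0.117 CPM. Without short-day drought replicate 1, the highest of these, the fall was larger (-8.18). RFT1 went from 4.39 ± 1.29 CPM to 0 counts in all 3 droughted libraries, at least 136-fold lower (adjusted p = 0.000233). Ehd1 was at 1.22 ± 0.0369 CPM with water and 0.861 ± 0.41 CPM under drought, a difference not past the test (-0.51 ± 0.503, adjusted p = 0.414). MADS14 fell by 1.495 ± 0.384 on the log2 scale (adjusted p = 0.00654), and MADS1, an E-class floral organ identity gene, dropped 18-fold from 41.7 ± 6.5 to 2.31 ± 1.33 CPM (adjusted p = 5.44e-05).

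PRR37, Hd1 and GI moved the other way in short days. PRR37 rose from 5.401 ± 1.33 to 67.1 ± 3.41 CPM (log2 fold change 3.63 ± 0.17, adjusted p = 2.32e-07). Hd1 rose from 2.38 ± 0.285 to 9.75 ± 1.36 CPM (2.04 ± 0.158, adjusted p = 2.55e-06), and DTH8 fell by 3.29 ± 0.584 on the log2 scale (adjusted p = 0.000664). Ghd7 (-0.60, adjusted p = 0.209) and MADS15 (-0.06, adjusted p = 0.946) were not past the test. Of the 23 flowering genes 4 rose and 11 fell (4 and 11 adjusted over the list alone; camera adjusted p = 0.113). Of the 13 clock genes 5 rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.957), with a median of -0.332 (0.108 with library sizes only) against a mean of 0.919 and an upward test statistic. GI rose 49.5-fold, from 17.3 ± 2.59 to 856 ± 88.6 CPM (5.63 ± 0.29, adjusted p = 3.05e-07). The pseudo-response regulator gene PRR73 rose by 2.53, and LHY fell by 1.82 on the log2 scale.

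**Figure D2:**
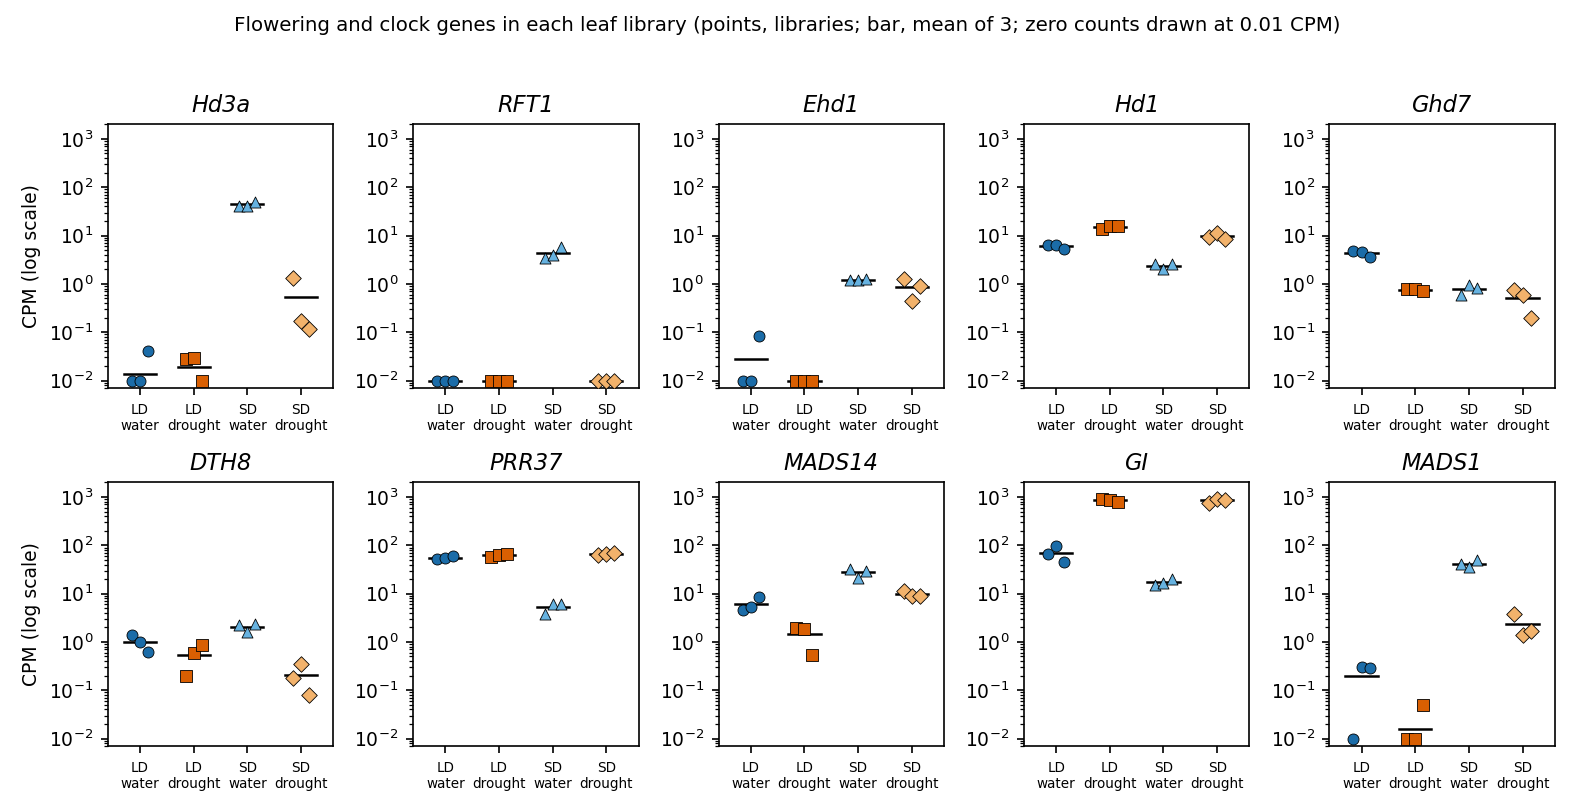
CPM (log axis) of 8 flowering genes, the clock gene GI and the floral organ gene MADS1 in each library, with points for the 3 libraries of a group (LD, long days; SD, short days) and a bar for their mean. Zero counts are drawn at 0.01 CPM. Hd3a lies at 44.5 CPM on average in short-day watered leaves and at 0.544 CPM in short-day drought leaves, while GI lies at 853 and 856 CPM in the droughted groups.

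The same 3 dehydration genes rose by orders of magnitude in short days. RAB16A rose from 15.9 ± 1.37 to 6331 ± 1300 CPM (log2 fold change 8.64 ± 0.631), LEA3 from 5.96 ± 1.74 to 2925 ± 539 CPM (8.94 ± 0.588) and SALT from 1.41 ± 0.261 to 527 ± 363 CPM (8.54 ± 1.13), with adjusted p of 9.23e-05 or less. The counts of the dehydration list were 14 raised and 2 lowered of 18 (camera adjusted p = 3.62e-05; adjusted p = 0.263 with an estimated correlation). TPP1 fell to 3 counts (ratio 19.2, counting interval 6.16 to 96.2). In the ABA list 20 of 34 genes rose and 7 fell (20 and 8 adjusted over the list alone; camera adjusted p = 0.0113, adjusted p = 0.38 with an estimated correlation). PP2C51 rose by 8.41 and SAPK3 by 3.06, and ABA8ox3 fell by 3.39. Drought-related transcription factors had 6 of 11 raised and 3 lowered (camera adjusted p = 0.199), with DREB2A at 2.12 and DREB1B at -5.87.

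Of 12 heat shock genes 10 rose and 1 fell in short days (10 and 1 adjusted over the list alone; median 3.91, camera adjusted p = 0.000434, adjusted p = 0.38 with an estimated correlation). HSP101 rose from 4.54 ± 0.723 to 150 ± 65.2 CPM (log2 fold change 5.05), HSP17.7 by 4.48 and HSP17.4 by 4.03. HSFA2a rose as well, from 0.865 ± 0.298 to 3.86 ± 0.377 CPM (2.14 ± 0.47, adjusted p = 0.00261), and the member that fell was HSFA2d (-2.68). Photosynthesis genes fell in 24 of 26 cases (26 adjusted over the list alone; median -2.28, camera adjusted p = 1.29e-08, adjusted p = 0.38 with an estimated correlation), with log2 fold changes of -2.37 for RCA and -1.64 for PSAH. CAB1R fell by 0.83 ± 0.255 on the log2 scale (adjusted p = 0.0165), a call lost with library sizes only (-0.38, adjusted p = 0.173), without short-day watered replicate 1 (adjusted p = 0.0627) and without short-day drought replicate 2 (adjusted p = 0.0613). All 9 chlorophyll breakdown and senescence genes rose (camera adjusted p = 0.000213, adjusted p = 0.263 with an estimated correlation), among them RCCR1 (3.26), NOL (2.49) and NYC1 (1.97).

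Antioxidant enzymes had 4 of 10 raised and 4 lowered (camera adjusted p = 0.705; CATB 2.46, SODA1 2.65, APX8 -1.28, or -0.82 with library sizes only). Aquaporins had 3 of 14 raised and 2 lowered (3 and 1 adjusted over the list alone; camera adjusted p = 0.957; median 0.17, mean -0.134), with PIP2;2 at -2.42 and the tonoplast channel gene TIP2;2 at 1.33. In sugar transport and metabolism 5 of 11 rose and 4 fell (camera adjusted p = 0.639). The sucrose synthase gene SUS2 rose by 1.37, and SWEET14 had a log2 fold change of -3.86. Pathogen response genes had 2 of 9 raised and 4 lowered (camera adjusted p = 0.343), including WRKY76 (-2.66) and the NPR1 homolog NH1 (-1.26, or -0.82 with library sizes only). Meristem and cell division markers had 2 of 4 lowered (camera adjusted p = 0.343) and guard cell markers 2 of 2 lowered (camera adjusted p = 0.165).

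Drought in short days raised 7249 loci and lowered 6766, 4363 and 4709 of them by at least 2-fold. The raised share was 51.7%, or 71.7% with library sizes only. Its log2 fold changes tracked those of drought in long days, which share no library with them (Pearson's r 0.854, Spearman's rho 0.833 across 23830 genes, which are not independent replicates). Both day lengths raised the same 5797 loci and lowered the same 5519, where independent lists would share 2361 and 2168, and 196 loci were called in opposite directions.

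**Figure D3:**
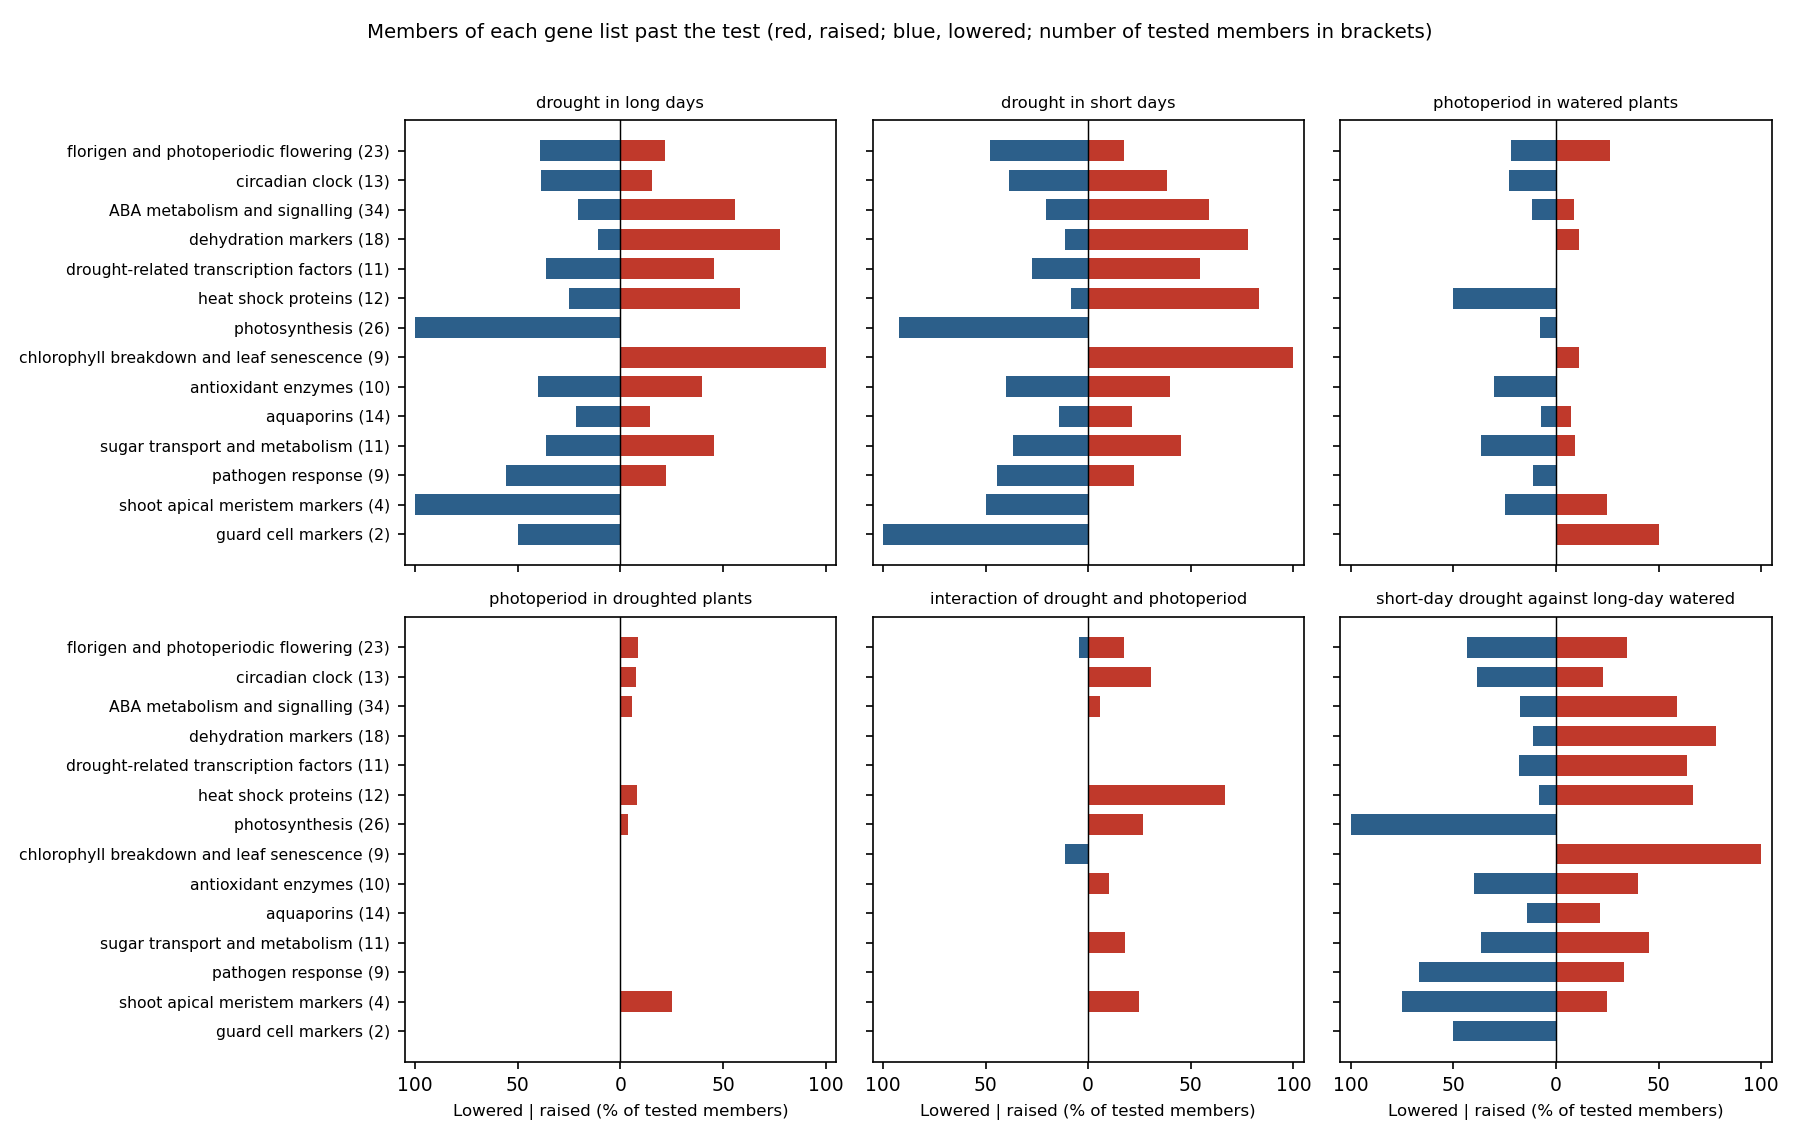
Share of the tested members of each of the 14 gene lists that rose (red, to the right) or fell (blue, to the left) in each comparison, in percent, with the number of tested members in brackets. Under drought all 9 chlorophyll breakdown and senescence genes rose in both day lengths, and 26 photosynthesis genes fell in long days and 24 in short days.

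Watered plants in short and long days were compared to ask what day length does on its own, and florigen genes rose in short days. Hd3a had 1 count in the 3 long-day libraries and 44.5 ± 5.34 CPM in short days, a ratio of 3020 (counting interval 541 to 119000; adjusted p = 0.000131). No locus that was past the test and met the CPM and overlap conditions of the naming rule rose more. RFT1 was at least 98.6-fold higher in short days (adjusted p = 0.00194). Ehd1 went from 2 counts to 1.22 ± 0.0369 CPM, a ratio of 41.2 (counting interval 11.1 to 345; adjusted p = 0.00291). Both long-day counts lay in replicate 3. MADS14 rose from 6.18 ± 2.14 to 27.6 ± 5.46 CPM (log2 fold change 2.16 ± 0.396, adjusted p = 0.00423). MADS1 rose 211-fold, from 0.195 ± 0.169 to 41.7 ± 6.5 CPM (7.72 ± 0.666, adjusted p = 0.000103). PRR37 fell by 3.36 ± 0.168 on the log2 scale (adjusted p = 6.69e-06), Ghd7 fell by 2.45 ± 0.377 (adjusted p = 0.00175) and Hd1 fell by 1.33 ± 0.157 (adjusted p = 0.000459).

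Of the 23 flowering genes 6 rose and 5 fell in short-day watered leaves (8 and 5 adjusted over the list alone; 8 and 6 without long-day watered replicate 3; camera adjusted p = 0.483). DTH8 (1.06, adjusted p = 0.163) and MADS15 (2.41, adjusted p = 0.0878) were not past the test, although MADS15 was past it under edgeR's likelihood ratio test (adjusted p = 0.0258) and without long-day watered replicate 3 (3.90, adjusted p = 0.0452). Phytochrome C (PHYC), a red-light receptor gene, rose by 1.30. In the clock list 3 of 13 genes fell and 0 rose (camera adjusted p = 0.0983): PRR37, PRR73 (from 368 ± 43 to 51.0 ± 3.25 CPM, log2 fold change -2.85, adjusted p = 6.69e-06) and GI (from 70.2 ± 26.2 to 17.3 ± 2.59 CPM, -2.02 ± 0.248, adjusted p = 0.000584). The hour of harvest is not given in the sources used here, and the levels of these genes follow the time of day.

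Of 12 heat shock genes 6 were lower in short days and 0 higher (7 lowered adjusted over the list alone; median -1.27, camera adjusted p = 0.00863, adjusted p = 0.875 with an estimated correlation). HSFA2a fell from 7.98 ± 3.59 to 0.865 ± 0.298 CPM (log2 fold change -3.19 ± 0.481, adjusted p = 0.00167) and HSP17.4 from 21.3 ± 7.52 to 2.52 ± 0.934 CPM (-3.08, adjusted p = 0.00128). Without long-day watered replicate 3 the count was 7 lowered. Of the ABA list 3 rose and 4 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.889; 5 and 1 with library sizes only), among them ABA8ox2 (1.88) and PP2C08 (-2.19). The dehydration list had 2 of 18 raised, DHN1 by 0.83 (adjusted p = 0.0114; camera adjusted p = 0.242). Of the drought-related transcription factors, 0 of 11 passed (camera adjusted p = 0.889). Of the 26 photosynthesis genes 2 fell (0 adjusted over the list alone; camera adjusted p = 0.288). Of the antioxidant list 3 of 10 fell (4 raised and 5 lowered adjusted over the list alone, and 3 and 3 with library sizes only; camera adjusted p = 0.709), including the cytosolic peroxidase gene APX2 (-1.496). In the sugar list 1 of 11 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.177), including SWEET13 (-1.99, adjusted p = 0.000354). Without long-day watered replicate 3 the raised and lowered counts were 1 and 3 for the clock list, 5 and 4 for ABA, 3 and 0 for dehydration markers and 2 and 0 for drought-related transcription factors. They were 0 and 1 for photosynthesis and 2 and 3 for antioxidant enzymes.

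In total 2696 loci were higher and 2875 lower in short-day than in long-day watered leaves, 1138 and 1379 of them by at least 2-fold, and the raised share was 48.4% (60.4% with library sizes only). The count of 5571 fell to 3050 without short-day watered replicate 2 and to 3546 when only the libraries compared were fitted.

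The comparison of droughted plants asks what is left of the day-length effect under drought. Between short-day and long-day droughted leaves 110 loci were higher and 16 lower, 95 and 10 of them by at least 2-fold, while 2915 had an unadjusted p under 0.05. Ehd1 was at least 32.1-fold higher in short days (0 counts in long days, 0.861 ± 0.41 CPM in short days; adjusted p = 0.0252). MADS14 was higher by 2.77 ± 0.418 on the log2 scale (1.44 ± 0.791 against 9.80 ± 1.47 CPM, adjusted p = 0.0261). MADS1 went from 2 counts to 2.31 ± 1.33 CPM, a ratio of 131 (counting interval 35.9 to 1090; adjusted p = 0.0126). For Hd3a the ratio was 31.9 (counting interval 8.4 to 270), from 2 counts to 0.544 ± 0.691 CPM, which was not past edgeR's quasi-likelihood test (adjusted p = 0.116) but was past its likelihood ratio test (adjusted p = 0.00139) and DESeq2 (adjusted p = 0.00592). Most of the Hd3a reads lay in short-day drought replicate 1 (1.34 CPM), without which the mean was 0.145 CPM and the ratio 8.36 (counting interval 1.73 to 79.5). RFT1 had 0 counts in both groups.

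GI stood at 853 ± 61.1 and 856 ± 88.6 CPM in the droughted groups (adjusted p = 0.997), and PRR37 at 62.3 ± 3.31 and 67.1 ± 3.41 CPM (log2 fold change 0.11, adjusted p = 0.869). Hd1 (-0.62, adjusted p = 0.0997), Ghd7 (-0.55, adjusted p = 0.656), DTH8 (-1.36, adjusted p = 0.386) and MADS15 (1.07, adjusted p = 0.656) were not past the test. Hd1 was past it under DESeq2 (adjusted p = 0.00452) and the likelihood ratio test (adjusted p = 0.039). Other calls in the lists were the clock gene PRR95 (1.09, adjusted p = 0.0281), ABA8ox3 (1.64, adjusted p = 0.0252) and HSFA2a (2.96 ± 0.485, adjusted p = 0.033). Of the 26 photosynthesis genes 1 was past the test over all genes and 19 adjusted over the list alone (all raised; median 0.999, camera adjusted p = 1.55e-17, adjusted p = 0.258 with an estimated correlation). Heat shock genes had 1 of 12 raised (4 adjusted over the list alone; median 0.813, camera adjusted p = 1.12e-05, adjusted p = 0.258 with an estimated correlation). The ABA list had 2 of 34 raised (2 adjusted over the list alone; camera adjusted p = 0.000443, adjusted p = 0.258 with an estimated correlation), and aquaporins had 0 of 14 raised (1 adjusted over the list alone; camera adjusted p = 0.0317, adjusted p = 0.258 with an estimated correlation). The meristem list had 1 of 4 raised (3 adjusted over the list alone; camera adjusted p = 1.12e-05, adjusted p = 0.045 with an estimated correlation). Over all comparisons this was the only list call that held with an estimated correlation. The 4 tested members of this list were MADS1 and cell division genes, as its members OSH1, OSH15 and MADS34 did not pass the filter.

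The total of 126 loci depended on single libraries: it was 3 without long-day drought replicate 1, 50 without long-day drought replicate 2, 9 without long-day drought replicate 3, 17 without short-day drought replicate 1, 132 without short-day drought replicate 2 and 243 without short-day drought replicate 3. With a library outside the comparison left out of the fit, the total was 516 without long-day watered replicate 3 and 40 without short-day watered replicate 1. The calls of Ehd1, MADS14, MADS1, PRR95, ABA8ox3 and HSFA2a each ended without long-day drought replicate 1 (adjusted p = 0.0794, 0.0737, 0.0732, 0.129, 0.0871 and 0.0717). Those of Ehd1, MADS14, PRR95, ABA8ox3 and HSFA2a also ended without long-day drought replicate 2 (adjusted p = 0.0595, 0.0672, 0.0997, 0.0703 and 0.091) and without short-day drought replicate 1 (adjusted p = 0.0925, 0.1, 0.123, 0.1 and 0.103). Those of Ehd1, MADS1, PRR95, ABA8ox3 and HSFA2a ended without long-day drought replicate 3 (adjusted p = 0.102, 0.0791, 0.0522, 0.145 and 0.18), and those of PRR95 and HSFA2a without short-day drought replicate 2 (adjusted p = 0.0578 and 0.0555). None of the 6 was past the test when only the libraries compared were fitted.

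The interaction asks where the drought effect differed between the 2 day lengths, which is equally where the day-length effect differed with water supply. PRR37 rose under drought in short days and was not past the test in long days, with a difference in log2 fold change of 3.46 ± 0.222 (adjusted p = 0.000257). The difference was 2.75 ± 0.191 for PRR73 (adjusted p = 0.00026) and 2.03 for GI (adjusted p = 0.00688). HSFA2a fell in long days and rose in short days, a difference of 6.15 ± 0.683 (adjusted p = 0.00134). HSP17.4 was at 21.3 ± 7.52 and 21.7 ± 10.4 CPM in long days but went from 2.52 ± 0.934 to 41.3 ± 10.3 CPM in short days (4.00, adjusted p = 0.00418). For Hd3a the difference was -6.53 ± 3.26 (adjusted p = 0.231), with 1 and 2 counts in long days. It was past the threshold under DESeq2 (adjusted p = 0.0066), limma-voom (adjusted p = 0.0192) and edgeR's likelihood ratio test (adjusted p = 0.0185), and without short-day drought replicate 1 (-8.41, adjusted p = 0.0196). RFT1, with 0 counts in 3 of the 4 groups, was not past edgeR's quasi-likelihood test (adjusted p = 1) and was past DESeq2 (adjusted p = 0.000786) and limma-voom (adjusted p = 0.00199).

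Other flowering genes with an interaction were MADS50 (1.02, adjusted p = 0.00563), MADS18 (1.70, adjusted p = 0.0138) and the phytochrome gene PHYA (-0.78, adjusted p = 0.0162). Ghd7 at 1.90 ± 0.534 was at the threshold (adjusted p = 0.0496) and lost its call under limma-voom (adjusted p = 0.0666), with no filter (adjusted p = 0.072), with library sizes only (adjusted p = 0.0648) and without each library except long-day watered replicate 3 and short-day drought replicate 3. Differences for Ehd1 (2.47, adjusted p = 0.31), Hd1 (0.71, adjusted p = 0.0622), DTH8 (-2.42, adjusted p = 0.0797), MADS14 (0.61, adjusted p = 0.517) and MADS15 (-1.33, adjusted p = 0.524) were not past the test. That of Hd1 passed under DESeq2 (adjusted p = 0.023) and without long-day watered replicate 3 (adjusted p = 0.029), and that of DTH8 under DESeq2 (adjusted p = 0.0299) and without long-day drought replicate 1 (adjusted p = 0.0426). The flowering list had 4 raised and 1 lowered of 23 (5 and 4 adjusted over the list alone; 5 and 3 without long-day watered replicate 3; camera adjusted p = 0.819). The clock list had 4 of 13 raised and 0 lowered (camera adjusted p = 0.00789, adjusted p = 0.147 with an estimated correlation).

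Heat shock genes had 8 of 12 with a more positive drought response in short days and 0 with a more negative one (9 and 0 adjusted over the list alone; median 2.03, camera adjusted p = 9.88e-06, adjusted p = 0.577 with an estimated correlation), including HSP17.7 (3.15, adjusted p = 0.0127). Of the 26 photosynthesis genes 7 had a more positive drought response in short days and 0 a more negative one (14 and 0 adjusted over the list alone; median 1.33, camera adjusted p = 3.57e-08, adjusted p = 0.577 with an estimated correlation), with CAB1R at 1.77 (adjusted p = 0.015). Single members of other lists were PP2C08 (2.78, adjusted p = 0.0154), OSL2 (-0.99, adjusted p = 0.0268), APX2 (1.84, adjusted p = 0.0153), SWEET13 (1.44, adjusted p = 0.0171) and the cyclin gene CYCB1-1 (3.11, adjusted p = 0.00544). The dehydration markers (camera adjusted p = 0.552) and drought-related transcription factors had 0 members past the test, and 1 lowered each without long-day watered replicate 3. The call of OSL2 ended without long-day watered replicate 2 (adjusted p = 0.0562) and without long-day drought replicate 1 (adjusted p = 0.0607) or 2 (adjusted p = 0.0658), short-day watered replicate 2 (adjusted p = 0.0607) or short-day drought replicate 3 (adjusted p = 0.0504). That of APX2 ended without short-day watered replicate 2 (adjusted p = 0.0502).

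In all, 1269 loci had a more positive and 983 a more negative drought response in short days, a raised share of 56.3% that turned to 33.8% with library sizes only. The total of 2252 was 4074 without long-day watered replicate 3, 4019 under DESeq2, and between 1113 and 1476 without any of long-day watered replicate 2, the long-day drought replicates, short-day watered replicates 1 and 2 or short-day drought replicate 1.

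Droughted plants in inductive short days were also set against watered plants in long days, which differ in both treatments. Hd3a was higher in the former (1 count against 0.544 ± 0.691 CPM, a ratio of 38.4 with a counting interval of 6.6 to 1540; adjusted p = 0.00977). Without short-day drought replicate 1 the ratio was 10.1 (counting interval 1.4 to 441). Ehd1 was higher too (2 counts against 0.861 ± 0.41 CPM, a ratio of 28.6 with a counting interval of 7.66 to 240; adjusted p = 0.000859). MADS1 rose by 3.56 ± 0.662 (adjusted p = 0.000806). Ghd7 fell by 3.05 ± 0.386 (adjusted p = 5.24e-05), DTH8 by 2.24 ± 0.593 (adjusted p = 0.00688) and MADS50 by 2.34 (adjusted p = 2.5e-07), and Hd1 was 0.70 higher (adjusted p = 0.00187), or 1.25 with library sizes only. PRR37 (0.28, adjusted p = 0.131) and MADS14 (0.66, adjusted p = 0.155) were not past the test but were with library sizes only (adjusted p = 0.00178 and 0.0154). RFT1 had 0 counts in both groups. LEA3 rose by 9.49 and RAB16D by 7.15, GI by 3.61 and HSP101 by 3.59, while RCA fell by 2.38 on the log2 scale.

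Of the lists, dehydration markers (14 of 18 raised, 2 lowered; camera adjusted p = 2.94e-05, adjusted p = 0.268 with an estimated correlation), the ABA list (20 of 34 raised, 6 lowered; camera adjusted p = 0.0127, adjusted p = 0.53 with an estimated correlation), photosynthesis (26 of 26 lowered; camera adjusted p = 8.48e-09, adjusted p = 0.547 with an estimated correlation) and chlorophyll breakdown (9 of 9 raised; camera adjusted p = 0.000231, adjusted p = 0.268 with an estimated correlation) passed. Heat shock genes (8 of 12 raised, 1 lowered, or 9 and 2 adjusted over the list alone and 8 and 2 without long-day watered replicate 3) passed at camera adjusted p = 0.0447, which was 0.607 as adjusted p with an estimated correlation and 0.0545 with a term for libraries 9 to 12. The flowering list had 8 raised and 10 lowered (12 and 6 with library sizes only; 8 and 7 without long-day watered replicate 3; camera adjusted p = 0.841). Altogether 7635 loci were higher and 7496 lower, 4774 and 5311 of them by at least 2-fold, a raised share of 50.5% (71.2% with library sizes only).

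The authors' deposited table of each comparison lists 23672 genes. At adjusted p of 0.05 the authors' deposited tables call 15779 genes for drought in long days, 14506 for drought in short days, 7471 for day length in watered plants, 1094 for day length under drought and 15509 for short-day drought against long-day watered plants. Of those calls, the fit used here made 90.5%, 88.2%, 68.8%, 11.3% and 90.0% in the same direction, and the authors' deposited tables shared 92.8%, 91.3%, 92.3%, 98.4% and 92.3% of its own calls. Calls at loci absent from the other side were counted as not shared, so these shares reflect unlike filters as well as unlike tests. Across the 22021 genes in both, the log2 fold changes of the authors' deposited tables and of this fit correlated at 0.9999 or more (genes are not independent replicates). The authors' deposited tables give Hd3a a log2 fold change of -6.39 for drought in short days and 11.26 for day length in watered plants.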

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

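Chosen only after the results were seen were the tests of splits of the libraries, of the ratio of the counts with 2 libraries left out, of the variance of the day-length effect, of the largest deviation among clock genes, of partial drying, of meristem tissue and of reads from related genes. At 2252 loci the drought effect differed between the 2 day lengths by the test of the interaction. These are set out here because the effects of 1 treatment differed between groups. The same test reads equally as a day-length effect that differs with water supply, and it cannot tell the 2 readings apart. Among named genes the difference in log2 fold change (short days minus long days) was 1.90 for Ghd7, 3.46 for PRR37, 1.02 for MADS50, 1.70 for MADS18, -0.78 for PHYA, 2.75 for PRR73, 2.03 for GI, 1.16 for PRR95, 2.78 for PP2C08, 0.97 for PP2C06, 6.15 for HSFA2a, 4.00 for HSP17.4, 3.15 for HSP17.7, 1.88 for HSFA2c, 1.77 for CAB1R, -0.99 for OSL2, 1.84 for APX2, 1.44 for SWEET13 and 3.11 for CYCB1-1. The lists that differed were the clock (camera adjusted p = 0.00789), heat shock proteins (9.88e-06) and photosynthesis (3.57e-08), none of them with an estimated correlation. A signal outside the gene counts was the share of reads assigned to no gene, which averaged 3.58% in the 6 droughted libraries against 3.20% in the 6 watered libraries.

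Day length changed 5571 loci in watered plants and 126 in droughted plants. Depth was argued against: with all libraries thinned to 1 depth, the count in watered plants was 47.7 times that in droughted plants. A wider spread between droughted libraries was argued against as the whole cause by loci picked in watered plants and measured in left-out replicates. The slope of their day-length differences on the effect fitted in watered plants was 0.0992 as large in droughted as in watered plants (0.0457 to 0.134 by replicate). This slope shows that the watered pattern was not kept under drought. It does not measure effects at other loci or in other directions. A part played by long-day watered replicate 3 stays open: without it the counts were 6529 and 516, a ratio of 12.7. That ratio ran from 6.96 to 86.47 when a further library was left out, on both sides of the 10 set against this explanation. A smaller day-length response under drought fits these values: over all tested loci the variance of the day-length effect, from differences that share no library, was 0.192 as large in droughted as in watered plants. This ratio was -0.0167 to 0.344 with 1 library left out, and 0.169 without long-day watered replicate 3. The test set in advance, the share of loci with a called interaction that had the larger day-length effect in watered plants (85.1%), is not used, because those loci were picked by the difference itself. A smaller response stays a hypothesis, as the growth chambers and soil drying of each group may differ in ways the labels do not give.

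Long-day watered replicate 3 stood apart from its group. Partial drying was argued against by a correlation of 0.0337 between its deviation and the drought effect in short days. A batch of libraries 9 to 12 cannot be told apart from a difference in that library alone. The deviation of long-day watered replicate 3 correlated with those of libraries 11 and 12 at 0.307 and 0.302, and with that of library 10 at -0.136. The average was 0.158. Harvest at another time of day stays open as well. The median deviation of the clock genes lay at percentile 32.2 among random lists, under the 75 set against this explanation, but that bound was wrong, because a shift in hour moves only the clock genes that change at that hour. TOC1 was at 43.4 CPM in this library against 10.15 and 12.9 in the other replicates, and LUX at 6.47 against 0.525 and 1.68. The largest deviation in the list lay at percentile 84. The design names no biological difference between replicates of a group, so none was tested.

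MADS1 reached 41.7 CPM in short-day watered leaves. Reads from MADS14, MADS15 and MADS18 were argued against, as the fold of MADS1 over long-day watered leaves was 37.4 times the largest of theirs. Reads from other MADS genes stay open, because no others were compared. Meristem or inflorescence tissue in the samples stays open: its markers OSH1 and OSH15 together were at 0.204 CPM, below the 1 CPM set for such tissue and above the tenth of that set against it. Both markers had 0 counts in short-day watered replicate 3, where MADS1 was highest (48.7 CPM). Nor did the cell division genes rise with MADS1 in watered leaves: CYCB1-1 fell by 1.53 ± 0.338 (adjusted p = 0.00968), and CDKB2-1 (-0.95, adjusted p = 0.127) and CDKB1-1 (-0.06, adjusted p = 0.764) were not past the test. The 4 tested members of the meristem list are MADS1 and these genes. In droughted plants 3 of them were higher in short days, adjusted over the list alone (median 1.1). The values in watered leaves go against such tissue without excluding it, as most are near the floor and a fall in the leaf itself could hide a small rise. Those in droughted plants do not go against it. Expression in the leaf itself may equally account for it and was not tested.

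Other splits of the same 6 libraries were tried for the 5 comparisons of group pairs. Each other split mixes both groups on each side, so the difference between the groups enters the spread within a side. Few calls are then left by construction, and such counts do not measure how many calls chance would give. The 10 splits of 3 against 3 are too few for a share under 0.05; in each comparison 1 split, the real one, gave as many loci, and the highest other count was 0 for drought in long days, 0 for drought in short days, 2 for day length in watered plants, 3 for day length in droughted plants and 0 for short-day drought against long-day watered plants. For the interaction 4 of 100 splits, the real one included, gave at least 2252 loci, and the highest other gave 2843. The 9 other splits that kept the real grouping of the watered libraries gave 1019 to 2843 loci. The count thus follows how the watered libraries are grouped and says little about the droughted ones. The remaining 90 splits gave at most 5 loci, but they mixed the watered groups, which again puts the difference between these groups into the spread.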

How the results depend on the processing

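Chosen only after results were seen were the settings with library sizes only, with thinned counts and with a library outside the comparison left out. The counts of changed loci for drought in long days, drought in short days and short-day drought against long-day watered plants stayed within 1.5 times their value in every setting run (14123 to 15610, 12315 to 13446 and 13800 to 15342 with 1 compared library left out). With library sizes only, the raised share of the interaction calls turned from 56.3% to 33.8%, and the balances of raised and lowered members turned in several lists, among them flowering and clock genes for drought in long days. Of 245 results for named genes, 205 kept their direction and their side of the threshold in every setting where they were compared. RLE and upper-quartile factors changed none. Named genes were not compared with thinned counts or at the stricter threshold for adjusted p. Under the alternative filter by CPM, 233 of the 245 results had a value.

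The count for day length in watered plants (5571) was 3546 with only the libraries compared, 2358 at the threshold of 0.01 and 3050 to 6529 with 1 library left out, the lowest without short-day watered replicate 2 and the highest without long-day watered replicate 3. For day length in droughted plants (126) it was 957 under DESeq2, 674 under the likelihood ratio test, 5 with only the libraries compared, 13 at 0.01 and 3 to 243 with 1 library left out, the lowest without long-day drought replicate 1 and the highest without short-day drought replicate 3. Of the libraries not compared there, it was 516 without long-day watered replicate 3, 53 without replicate 2 of that group, and 40 and 45 without short-day watered replicates 1 and 3. For the interaction (2252) it was 4019 under DESeq2, 519 at 0.01 and 1113 to 4074 with 1 library left out, the lowest without short-day watered replicate 2 and the highest without long-day watered replicate 3. A stricter threshold calls fewer loci by construction, and for the rest the cause was not tested.

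The number of lists past the threshold went from 3 to 0 in drought in long days with an estimated correlation in camera, from 5 to 0 in drought in short days, from 1 to 0 for day length in watered plants, from 5 to 1 in droughted plants, from 3 to 0 in the interaction and from 5 to 0 in short-day drought against long-day watered plants. With fry, which asks whether a list moves one way and does not compare it with other genes, the numbers were 11, 13, 4, 3 and 12 for these comparisons other than the interaction. In the interaction fry passed the clock (adjusted p = 0.000421), heat shock (adjusted p = 0.0128) and meristem lists (adjusted p = 0.0115). Photosynthesis did not pass with fry there (adjusted p = 0.0648).

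The correlation of the drought effects (0.854) was 0.902 over loci of at least 10 CPM. At the threshold of 0.01, the shared part of the calls in the authors' deposited tables and of the calls made here was 83.9% and 94.5% for drought in long days, 81.2% and 93.8% in short days, 44.2% and 95.4% for day length in watered plants, 2.22% and 100% in droughted plants, and 83.6% and 94.4% for short-day drought against long-day watered plants. These shares again counted calls at loci absent from the other side as not shared. Depth limits what can be said of Hd3a, RFT1 and Ehd1 in long days, where 3 counts over a group are 0.0268 to 0.0445 CPM.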

Other observations

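The correlation of the day-length effects and the spread within each group were computed only after the results were seen. The day-length effects in watered and in droughted plants, which share no library, correlated at 0.107 across genes (Spearman's rho 0.0697; genes are not independent replicates), against 0.854 for the drought effects in long and short days. Of the loci called for day length in both, 22 were raised in both and 5 lowered in both, where independent lists would share 12.4 and 1.93, and 27 were called in opposite directions. With 27 opposite calls against 22 and 5 in the same direction, these overlaps show no agreement in direction. The number of opposite calls that independent lists would give was not computed.

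The spread between replicates differed by group. The biological coefficient of variation fitted within a group was 37.1% in long-day watered, 18.5% in long-day drought, 18.3% in short-day watered and 28.6% in short-day drought libraries. In the long-day watered group replicates 1 and 2 correlated at 0.985, against 0.938 and 0.952 with replicate 3, so replicate 3 carries much of that spread. Because the fit pools the groups, tests against long-day watered libraries use less spread than that group showed. Tests without that group still draw on its spread.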
